A study of Mus musculus with 6 samples.

How the data were processed

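Chromatin immunoprecipitation followed by sequencing (ChIP-seq), which maps where a protein sits on DNA, was done in mouse bone marrow progenitors (Lin-Sca-1+c-Kit+ cells) transformed in culture with the MLL-AF9 fusion oncogene. Per the labels, the series holds 6 libraries in 6 groups of 1 library each: PU.1 and C/EBPα, each without treatment and with an LSD1 inhibitor, LSD1 itself without treatment, and an input library without antibody. The cells grew in medium with interleukin-3 at 10 ng/mL, interleukin-6 at 10 ng/mL and stem cell factor at 20 ng/mL, per the labels' protocols. The labels' protocols name GSK-LSD1 as the LSD1 inhibitor of the study and give neither its dose nor its duration for these libraries.

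The file used here is 1 list of genomic intervals for the whole series, deposited by the authors. It has 3 columns, chromosome, start and end, and holds no header, region name, signal, read count, fold or p-value. The calculations used the start and end positions, in base pairs, as the authors deposited them. Per the submitters' processing notes, Bowtie2 2.2.2 (a read aligner), bedtools (a tool for interval files) and the mouse build mm9 were used, with no role or order stated. The peak caller, its threshold, which libraries gave the list and how a region qualified as dynamic (the word the list carries in its name) are not given in the sources used here. The list is a single combined set, so no interval belongs to a sample, and there were 0 columns of values per sample.

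Several planned results need more than positions. Direction of change per region, peak categories, annotation to genes, gene lists and motif counts (5 results) were planned before the data were examined and were not computed: the first and second need values or names per region, the others an mm9 genome or annotation. A gene table on assembly GRCm38.p6 was compared with the list and not used to assign genes, because the processing notes name mm9. In that comparison 29 intervals on 6 of the 20 chromosomes ended beyond the last gene of the table. This can also happen on a matching build, so it does not tell the builds apart. The 14 gene lists and 10 motifs fixed beforehand were therefore not used here. Read depth per library and its effect on which regions were called are unknown here, and no interval or floor that needs depth is given.

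The 3 results computed were the size and width of the region set, its distribution over chromosomes and its clustering. For printing, starts were converted to 1-based positions. The length of a chromosome was taken as the largest interval end on it. Region counts per chromosome were compared by a permutation test with 100000 random multinomial draws of the same number of regions, with chance proportional to length, two-sided, with Benjamini-Hochberg adjustment over 20 chromosomes and a threshold of 0.05. Clustering was measured as the percentage of regions with another region's centre within 12500 bp (called the stitching distance), against 10000 random placements of the same number of centres per chromosome, uniform from the first base to the largest end, one-sided (a permutation of positions). Placements may put centres closer together than any pair in the list. A 95% interval was added by resampling 5 Mb windows 10000 times (the partial last window of each chromosome included), which keeps the unevenness along chromosomes; this was chosen after the data were seen. Medians of widths carry a 95% binomial order-statistic interval and were compared by permutation tests with 100000 resamples. Regions are not replicates: the p-values for chromosomes and clustering describe this list against a model of random positions, those for widths compare sets of regions within it, and none tests the treatment, since each group has 1 library.

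By the rule set beforehand for a list without gene names, the regions named are the 10 widest intervals and the 10 groups with the most intervals, where intervals were chained when consecutive centres were at most 12500 bp apart and ties went to the smaller span. Alternatives changed the distance (5000 and 25000 bp), merging (touching, within 500 and within 1000 bp), chromosome length (first to last interval), the placement (each region moved at random within 1 Mb of its own place) and the chromosomes kept. Added after the data were seen were placement within 100 kb, merging within 5000 bp, regions up to 2000 bp wide, autosomes only (for the chromosome distribution and clustering; planned for size and width), counting groups and the resampling of windows.

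The tests were tested on simulated data of 4669 regions. Of 400 lists placed uniformly, 15 (3.75%) passed the clustering threshold, and 50 of 50 lists with 3% of regions moved beside another did. The chromosome test called X in 200 of 200 lists with X at 0.5 of its share and chromosome 2 in 169 of 200 lists with it at 1.25 of its share, and made any call in 7 of 200 lists that followed length. In the unchanged lists of both tests, regions were placed independently, as the tests assume, so those rates only check the calculation. They do not measure false calls in a list that is uneven along chromosomes, as this one is. The width test called 3 of 50 shuffled lists. It called 45 of 50 shuffled lists with 40 bp added to a random set of regions, as many as have a neighbour. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.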

Results

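The binding of PU.1 and C/EBPα, a pair of transcription factors that drive myeloid differentiation, was mapped by ChIP-seq in MLL-AF9-transformed mouse bone marrow progenitors with and without inhibition of LSD1. LSD1 (the Kdm1a protein) is a histone demethylase, and MLL-AF9 is a fusion oncogene of acute myeloid leukaemia. The 6 libraries comprised PU.1 and C/EBPα in untreated and inhibitor-treated cells, LSD1 in untreated cells, and an input library. The series title places the question at enhancers that depend on PU.1 and C/EBPα and their response to LSD1 inhibition. The measurement analysed here was the authors' combined list of peak regions, which its name describes as dynamic transcription factor peaks. The list gives positions on mm9 without signal or direction, so gain and loss of binding, PU.1 and C/EBPα, and treated and untreated cells were not separated here. Each group had 1 library, and no difference between treated and untreated cells has a replicate check.

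The list held 4669 regions on the 19 autosomes and chromosome X. They were mostly of similar size, with a median width of 962 bp (95% interval 954 to 970) and the central 50% between 829 and 1096 bp. The mean width was 1009 bp ± 343 (SD over regions), and the range ran from 226 to 6080 bp. Together the regions covered 4.71 Mb, which was 0.180% of the chromosome lengths summed up to the last region on each. They were sparse, with a median gap of 236.6 kb between neighbours on a chromosome. No pair of regions overlapped or touched, and the smallest gap between neighbours was 1003 bp.

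**Figure D1:**
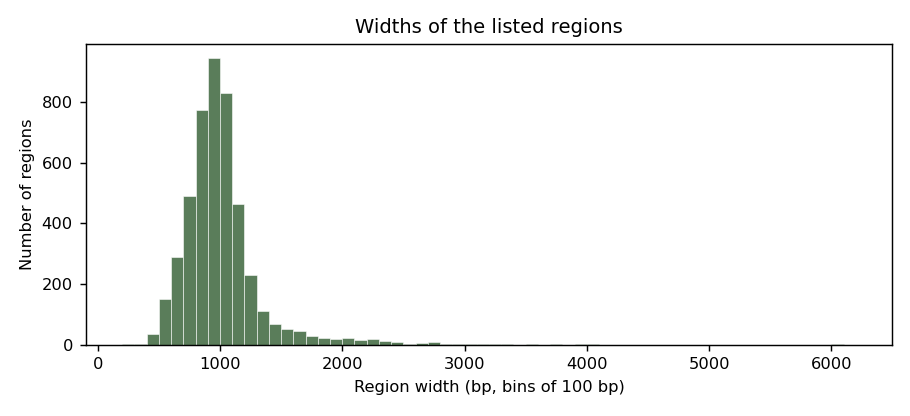
Histogram of region widths, with width in base pairs in bins of 100 bp on the x axis and the number of regions on the y axis. Most of the 4669 regions lie near the median of 962 bp, and a thin tail reaches 4053 bp, with 1 region beyond it at 6080 bp.

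The widths had a thin upper tail, in which 115 regions (2.46%) exceeded 2000 bp and none lay between 4053 and 6080 bp. The widest region lay on chromosome 8 from 124345730 to 124351809 and measured 6080 bp. Chromosome 2 held the next pair, a 4053 bp region from 5690274 to 5694326 and a 4010 bp region from 115598195 to 115602204. On chromosome 3, the region from 100858834 to 100862807 measured 3974 bp. The region on chromosome 7 from 85975568 to 85979321 measured 3754 bp, and the one on chromosome 16 from 58479841 to 58483412 measured 3572 bp. Chromosome 19 held a region of 3328 bp from 55939755 to 55943082. Chromosome 9 held a region of 3268 bp from 8179119 to 8182386 and one of 3226 bp from 32307288 to 32310513. The remaining one of the 10 widest, 3235 bp, lay on chromosome 4 from 5613609 to 5616843. Of these 10 regions, 2 had another listed region's centre within the stitching distance, the fixed distance used to chain neighbours, those on chromosomes 3 and 4, with centre distances of 8.69 and 4.36 kb. The genes around these positions were not analysed here.

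The regions were spread over every autosome, and chromosome X held far fewer than its length would give. X had 112 regions where 294.7 were expected from length, a ratio of 0.38 (95% interval 0.28 to 0.48 from resampled 5 Mb windows). That was 6.77 regions per 10 Mb, against 14.2 to 25.4 per 10 Mb on the autosomes. Full 5 Mb windows of X held 3.33 regions on average and 9 at most (33 windows), against 8.81 on average and 27 at most over all 517 windows of the 20 chromosomes. The adjusted p for X was 0.0004 by random draws, whose raw p of 2e-05 was the smallest they could give. By resampled windows the adjusted p was 0.004, from a raw p of 0.0002, which was also the smallest possible. By the permutation test with random draws, chromosome 19 (155 regions, ratio 1.43, adjusted p = 0.0004), chromosome 11 (260 regions, ratio 1.21, adjusted p = 0.0091), chromosome 13 (257 regions, ratio 1.20, adjusted p = 0.012) and chromosome 2 (386 regions, ratio 1.20, adjusted p = 0.0021) held more than length gave. Chromosome 12 held fewer, with 171 regions and a ratio of 0.80 (adjusted permutation p = 0.0091). The other 14 chromosomes had ratios between 0.86 and 1.13 and did not pass the threshold.

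Of these 6 calls, X alone remained when 5 Mb windows were resampled. The adjusted p was then 0.27 for chromosomes 2, 12 and 19, 0.33 for chromosome 13 and 0.37 for chromosome 11, and no autosome passed the threshold. With X left out, the same permutation test no longer called chromosomes 11 (ratio 1.16, adjusted p = 0.062) and 13 (ratio 1.15, adjusted p = 0.074), and it called chromosome 14 (ratio 0.82, adjusted p = 0.029).

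**Figure D2:**
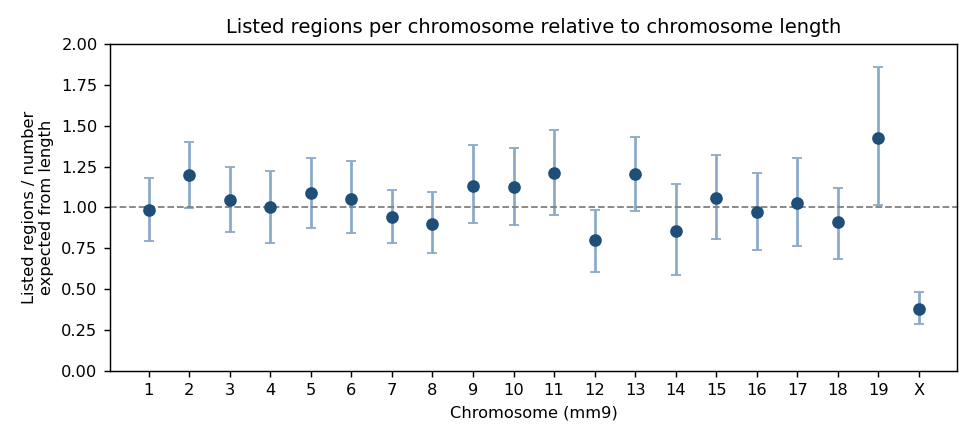
Listed regions on each mm9 chromosome divided by the number expected from chromosome length (y axis, linear), with 95% intervals from resampled 5 Mb windows as bars and a dashed line at 1. Chromosome X, at 0.38, lies below every autosome, the lowest of which is chromosome 12 at 0.80.

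**Figure D3:**
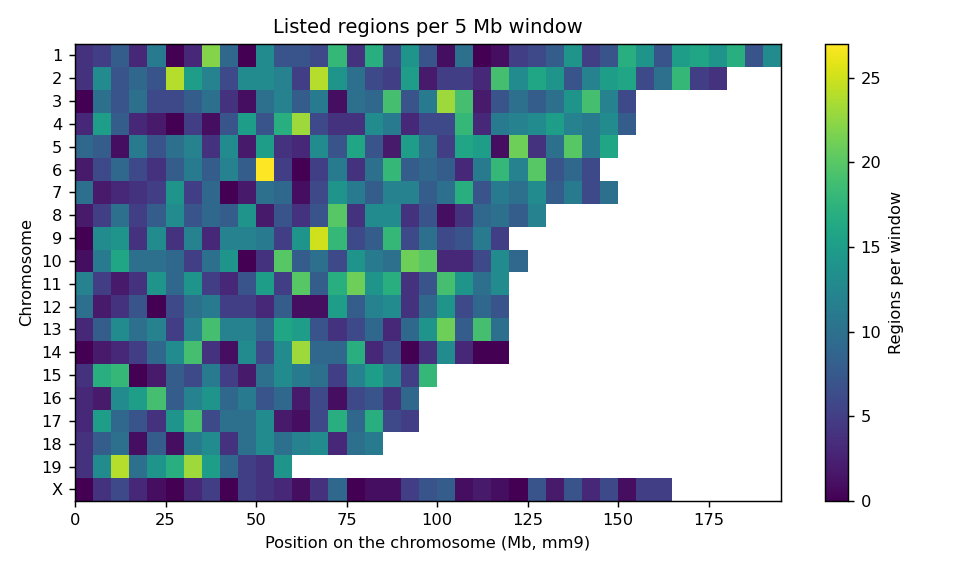
Number of listed regions in each full 5 Mb window (colour scale) by position on the chromosome (x axis, Mb, mm9), with 1 row per chromosome and white beyond the last full window. Windows of X stay at or below 9 regions, and the fullest window, with 27, lies on chromosome 6.

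Regions lay close to one another more often than random placement gave. Of the 4669 regions, 492 (10.5% ± 0.658, standard error from resampled windows, 95% interval 9.27% to 11.8%) had another region's centre within the stitching distance. Uniform placement gave 4.50% ± 0.420 (SD over 10000 placements), with a highest value of 6.21%, so the observed percentage was 2.34 times the mean (one-sided permutation p = 0.0001, the smallest that 10000 placements can give). When each region was moved at random within 1 Mb of its own place, which keeps broad differences in density, placements gave 6.19% on average and 8.33% at most. The excess over that model was 1.70 times (permutation p = 0.0001). It narrowed to 1.21 times for moves within 100 kb, whose placements averaged 8.68% (permutation p = 0.0002). When regions within 5000 bp were merged first, 5.63% of 4544 regions had a neighbour, against 4.39% of placed ones (permutation p = 0.0021). The placed centres were not merged and could lie within 5000 bp of each other, which raises the placed percentage by construction.

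By distance, the excess over uniform placement was 2.06-fold for nearest centres under 5 kb (176 regions), 2.85-fold from 5 to 10 kb (240 regions), 1.91-fold from 10 to 20 kb (311 regions) and 1.69-fold from 20 to 50 kb (764 regions). It was 1.16-fold from 50 to 100 kb (753 regions), and from 100 to 200 kb the ratio was 0.95. Against placement within 1 Mb, the ratios over these first 4 distance classes were 1.49, 2.10, 1.41 and 1.31, and the ratio from 50 to 100 kb was 0.97. Listed regions were at least 1003 bp apart from edge to edge, so their centres lay further apart still. Placed centres could lie closer, which lowers the ratios under 5 kb. The higher ratios from 5 to 10 kb therefore cannot be read as a preferred distance.

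**Figure D4:**
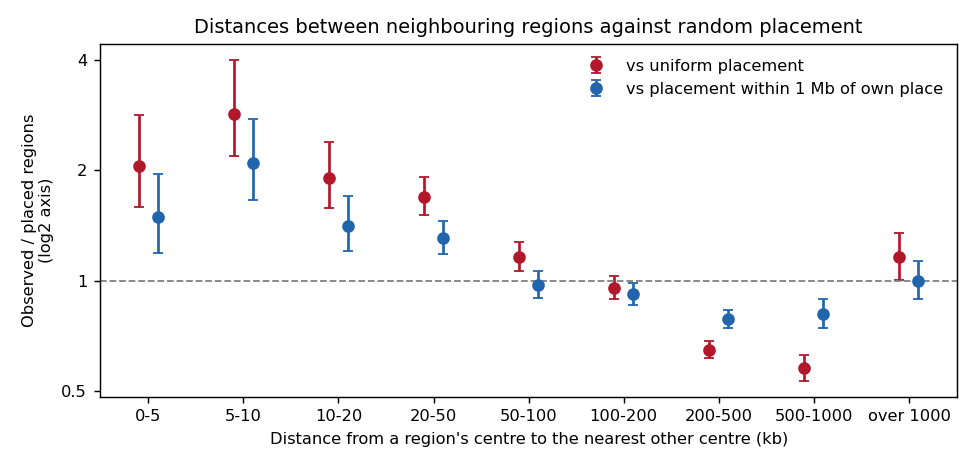
Number of regions by distance from their centre to the nearest other centre (x axis, kb), divided by the mean number in 2000 random placements (y axis, log2 scale); bars give the ratio to the central 95% of placements. The highest ratios, 2.85 (uniform placement) and 2.10 (placement within 1 Mb), are in the class from 5 to 10 kb. Ratios under 5 kb are lowered because listed regions are at least 1003 bp apart from edge to edge, with centres further apart, and placed centres may lie closer.

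The neighbouring regions formed 229 groups, where uniform placement gave 103.9 on average and 141 at most. Most were pairs (203), while 26 groups held at least 3 regions. Uniform placement gave 2.42 groups of that size on average and 10 at most, and placement within 1 Mb gave 5.23 on average and 15 at most (one-sided permutation p = 0.0001 in both cases, the smallest possible). The largest group held 5 regions within 29.6 kb on chromosome 3, from 100833209 to 100862807, and included the fourth widest region of the list. All 6 groups of 4 regions spanned between 17.0 and 30.9 kb. They lay on chromosome 2 from 140603763 to 140620730, on chromosome 15 from 12989054 to 13007226, on chromosome 14 from 64581229 to 64602458, on chromosome 18 from 62223665 to 62248311, on chromosome 13 from 38595066 to 38621313 and on chromosome 10 from 59715032 to 59745974. The tightest groups of 3 lay on chromosome 7 from 34680010 to 34687387 (7.38 kb), on chromosome 16 from 45224282 to 45231876 and on chromosome 1 from 80718847 to 80727539 (8.69 kb). Chromosome X held 4 groups, none among these 10.

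**Figure D5:**
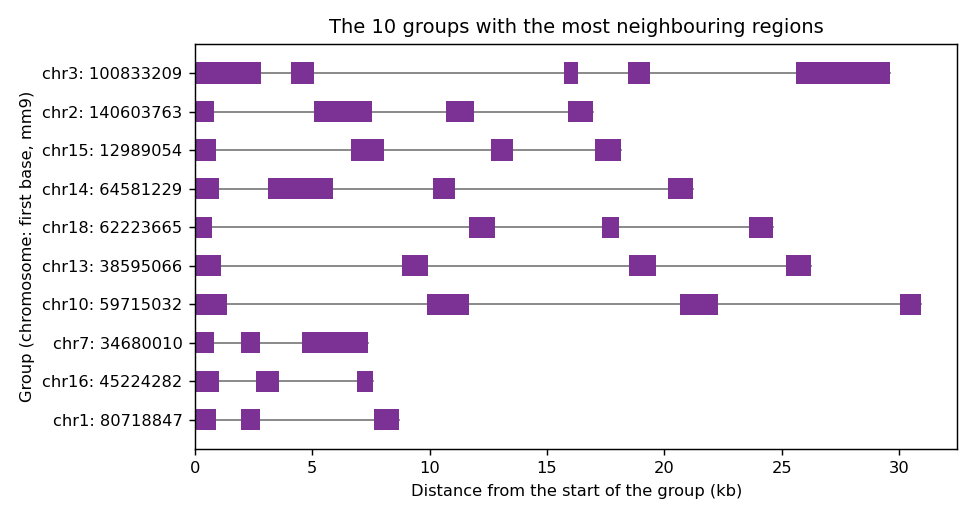
Maps of the 10 groups with the most regions, drawn to scale from the first base of each group (x axis, kb); boxes are listed regions and each row is labelled with its chromosome and first base on mm9. The group on chromosome 3 holds 5 regions within 29.6 kb, and the 3 shortest groups span 7.38 to 8.69 kb.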

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

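The alternatives beyond those planned, namely placement within 100 kb, merging within 5000 bp, regions up to 2000 bp wide, autosomes only for chromosome distribution and clustering, counting groups and resampling of 5 Mb windows, were chosen after seeing the data. The clustering percentage stayed above the mean of its placements, past the threshold, in all 28 alternatives, of which merging within 1000 bp changed nothing and autosomes only repeats leaving out X, at 1.21 to 2.42 times the placement mean. It lay between 10.2% and 10.8% when each of the 20 chromosomes was left out in turn, and was 9.71% among regions up to 2000 bp wide, 3.77% at 5000 bp and 18.6% at 25000 bp. Merging overlapping or touching regions, or those within 500 or 1000 bp, changed 0 regions, so those settings say nothing about stability. The number of regions was 4557 on the autosomes and 4544 after merging within 5000 bp, with median widths of 962 and 965 bp. The number of chromosomes that departed from length was 6 with the span from first to last interval, 7 when groups were counted and 4 of the autosomes with X left out. It moved to 1 (X) when 5 Mb windows were resampled, with 3 chromosomes at an unadjusted p under 0.05, and to 0 when the autosomes alone were resampled, with 1 at an unadjusted p under 0.05. Resampling keeps the unevenness along each chromosome that random draws ignore, which widens the error by construction. X kept its direction and its call in all the alternatives that included it, with ratios of 0.38 to 0.39. No paired analysis was possible because each group has 1 library and the list holds no values per library. No library could be left out for the same reason. The settings foreseen for direction of change, peak categories, gene annotation, gene lists and motifs were not run. The depth of the libraries is unknown here, so how far depth limits which regions were listed could not be assessed.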

Other observations

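The tests of the X pattern and the descriptions of 5 Mb windows and of the smallest gap were chosen after the counts per chromosome and the gaps were seen. Placement within 1 Mb was planned beforehand. Placement within 100 kb, the test of neighbours beyond 5000 bp and the test of widths in groups were added after the list had been opened, with their predictions written before the values they measure were computed. The regions were unevenly spread along chromosomes. Over 517 full 5 Mb windows with a mean of 8.81 regions, the variance was 3.42 times the mean, against 1.34 on average and 1.58 at most in 10000 uniform placements (one-sided permutation p = 0.0001, the smallest possible). The 5 Mb windows with the most regions were on chromosome 6 from 50000001 to 55000000, with 27 regions, and on chromosome 9 from 65000001 to 70000000, with 25 regions. At the other end, 20 windows held no region, where placements gave 1.12 on average and 6 at most. Of the 20 empty windows, 15 were on autosomes and 5 on X, and they included the first window of chromosomes 3, 9, 14 and X. Placements could fall anywhere from the first base, and stretches where no region can be called were not left out. How much such stretches add to the empty windows and to the variance is unknown here. The longest stretch without a region was 14.2 Mb on chromosome 14, from 107087367 to 121324541, followed by 10.6 Mb on X from 20509907 to 31063213. Of the 10 longest stretches, 3 were on X. These windows and stretches were chosen after their values were seen, and the genes in them were not analysed here.

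Chromosome X held 112 regions, 0.38 of the number its length gives. A few large empty stretches would leave the remaining windows as dense as on autosomes, but full 5 Mb windows of X that held any region averaged 3.93 (95% interval 3.07 to 4.82), against at least 7.39 on every autosome. That average follows from the mean of 3.33 over 33 full windows of X, 5 of them empty. Stretches that empty only part of a window are not addressed by it. Weaker signal on X might give narrower regions, and this stays open: the median width on X differed from the autosomal 962 bp by -3.0 bp (95% interval -46.5 to 27.5, two-sided permutation p = 0.91), and 112 regions do not narrow it further. The number of X copies in these cells, mappability and gene density on X were not tested, and no biological explanation was tested, since no group of the design bears on it.

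The clustering of regions could come from broad peaks written as several adjacent intervals, from broad differences in density or from finer ones. Pieces less than 5000 bp apart would put the excess at the shortest distances. Yet 6.77% of regions had their nearest neighbour between 5000 bp and the stitching distance away. Placements within 1 Mb gave 3.65% on average and 5.12% at most, so such pieces are not the whole of it. Pieces of wider domains could lie that far apart, so this test cannot exclude them. Merging within 5000 bp first lowered the ratio to uniform placements from 2.34 to 1.28. Part of that fall is built in, since the list was merged while placed centres could still lie within 5000 bp. Merging also joins split and separate regions alike, so the fall does not measure how much splitting adds. Density differences at the megabase scale gave 6.19% on average and 8.33% at most against the observed 10.5%, which leaves them as a part and not the whole. Differences at the 100 kb scale, which may follow gene-rich or open segments, gave 8.68% on average, and 1 of 10000 placements reached the observed value (10.58% at most). They cannot be told apart from closer grouping here, since moves of up to 100 kb keep part of any grouping. No biological explanation was tested, as the list does not tell PU.1 from C/EBPα or gained from lost regions. No other peak list was compared, so neither the clustering nor the low count on X can be tied to the regions being dynamic.

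Regions in groups were wider than lone ones, and no close pairs were listed. There were 0 gaps of 1000 bp or less between neighbours, where 2000 placements of the same widths within 1 Mb gave 24.3 on average and at least 11, while 43 observed gaps were above 1000 and up to 2000 bp. Placed regions could overlap, which listed ones never did, so the placed count may include overlapping pairs. These values describe the list and do not tell joining of close peaks from their removal. If wide intervals were joined neighbouring peaks, they would lie where regions are close together. The median width was 1002 bp (95% interval 979 to 1030) among the 492 regions with a neighbour within the stitching distance and 957 bp (950 to 965) among the 4177 others, a difference of 45.0 bp (two-sided permutation p = 0.0001). Widths over 2000 bp were found in 5.89% against 2.06%, the direction that joining would give. Most regions over 2000 bp were lone, as were most regions in the whole list. Of the 10 widest regions, 2 had a neighbour within the stitching distance, against 10.5% of all regions, and 10 regions are too few to compare. Stronger binding in groups might also widen regions, and the list has no signal to test it.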
